A study of Oryza sativa Indica Group with 9 samples.

How the data were processed

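Leaves of rice seedlings (Oryza sativa Indica Group, breeding line HT54) at the three-leaf stage were sampled after 0, 12 or 24 h at 45 °C, per the labels. Small RNA of 15 to 30 nt was recovered from a gel and sequenced, with 2 libraries per time point used here, numbered 1 and 3 in the labels. The labels describe the samples of a time point as independent and state that the submitters left out 1 small RNA library per time point as unsuitable. They do not say on what ground, so the spread between the remaining libraries may be smaller than that of all libraries made. The degradome, a library of 5′ ends of cleaved polyadenylated RNA, was sequenced once per time point, so its differences have no replicate check.

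The miRNA tables list raw reads per mature sequence, which the authors deposited as estimated counts, because a read that matches several positions was divided among them. Between 66.9 and 75.2% of the values of a library were whole numbers (tolerance 1e-06). The rule for dividing the reads, the read mapper, the miRNA database release and the genome build of the listed precursor coordinates are not given in the sources used here. The authors also deposited a normalized signal, which is the raw value times 1 constant per library. These constants were 1.80 and 0.753 at 0 h, 0.451 and 4.16 at 12 h, and 0.846 and 0.464 at 24 h (replicates 1 and 3). A table of read classes gives the authors' percent of all reads of a time point in each class, with 1 value per time point, so replicates were pooled or averaged, per the file headers. The deposited p-value of each miRNA comes from an analysis of variance over the 3 time points, and the deposited p-value of each cleavage site from a chi-square test over the 3 degradome libraries, per the file headers. For the degradome the authors deposited the read count at each predicted cleavage site, the same reads divided among matching transcripts, a signal in divided reads scaled to the raw reads of the library (TPB), and a score, the category of the site from 0 to 4. The alignment score of each listed miRNA and its site, also deposited, was at most 4. Category 0 is used in such tables for a site holding the highest signal of its transcript, and category 4 for a site with a single read. The target finder and its version are not given in the sources used here.

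The miRNA list held 588 entries for 483 distinct mature sequences, and each sequence was used once. Of these, 289 stood in the authors' table of known rice miRNAs, 118 in that of conserved miRNAs of other plants, 73 in that of new candidates, and 3 in none of them. Raw values were rounded to whole numbers. Sequences were also summed by family number, which gave 132 families, because near-identical members cannot be told apart by short reads. Names such as R+1 or 1ss20AT are the authors' and mark added bases or substitutions relative to the database entry.

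Sequences and families with at least 10 reads in at least 2 libraries were tested, which left 459 sequences and 124 families. The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, TMM scaling, 2-sided) with all 6 libraries in 1 fit, time point as the only factor and Benjamini-Hochberg adjustment with a threshold of 0.05. The fit was planned for whole-number counts, and the estimated counts were rounded for it. Standard errors (SE) are the log2 change divided by the square root of the F value. The common dispersion was 0.219, a biological coefficient of variation of 0.468. The prior degrees of freedom of the sequence fit were infinite. Its SE and p therefore rest on a spread shared over sequences and not on that of each sequence's own libraries. The family fit likewise shares its spread over families, so the SE and p of a family rest in part on other families. Levels are in CPM (read counts scaled to a common total after TMM scaling) with the SD of the 2 libraries. The floor of 3 counts corresponded to 78.4 and 28.7 CPM in the 0 h libraries, 20.3 and 195 CPM in the 12 h libraries, and 36.2 and 16.1 CPM in the 24 h libraries. Where a group had no read, the fold is a lower bound against 3 counts over the group.

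The design, the filters, the preset lists, the rule for named items and all alternatives except 1 were fixed before the data were examined. The lists were auxin response (miR160, miR167, miR390, miR393), copper response (miR397, miR398, miR408, miR528), nutrient response (miR395, miR399, miR827, miR169, miR2111), phase transition (miR156, miR172, miR529, miR535), leaf development (miR159, miR164, miR166, miR171, miR319, miR396), small RNA machinery (miR162, miR168), MADS-box regulation (miR444), restricted rice or monocot miRNAs (miR1425, miR820, miR1432, miR1423, miR1850, miR1862, miR1868, miR1876), triggers of phased small RNAs of the panicle (miR2118, miR2275), sequences of 23 or 24 nt, and passenger strands, taken as the less abundant strand, by the deposited arm, of each family in these lists, the restricted ones included. Lists were tested with fry (limma 3.58.1), whose directional p asks whether members move on balance 1 way and whose mixed p asks whether they change in either direction. Neither compares a list with other sequences. No sequence of miR395, miR399, miR2111, miR1868 or miR2275 was among the tested members of these lists. Camera with an estimated correlation was the alternative. Named sequences were, per contrast, the 10 largest rises and the 10 largest falls among those past the threshold with a mean of at least 50 reads in the higher group and no overlap of the libraries, or the 10 with the smallest p where fewer than 10 passed. Further named items were the 2 most abundant members of each list and up to 15 families past the threshold with a mean of at least 100 reads in the higher group. For the degradome the rule took the 10 category 0 sites with the most reads per library, the sites that met a rule of size, and the sites of well-known targets. Items named outside these rules are marked as chosen after their values were seen, except in the accounts of the lists, which also name members and families outside them without a mark.

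Degradome entries were merged into pairs of a miRNA family, or a new candidate, and a target locus, keeping the entry with the most reads. Reads were scaled to the raw reads of the library and are plotted per 10000000 of them. A pair met the rule of size when it had at least 10 reads in either library and a ratio of at least 4. Ratios carry exact 95% intervals conditional on the sum of the reads, shares carry Wilson intervals, and both, like the floors, cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Gene descriptions of the loci are the authors', since 0 of the 519 locus identifiers matched the reference gene table used here. The relation of miRNA change and degradome change across families was tested with 100000 permutations for 3 contrasts. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for these steps.

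The procedures were tested on simulated data. Counts of 459 sequences were drawn from the mean levels over all 6 libraries, the library depths and 1 common dispersion. At 24 h, 50 sequences per fold were changed, evenly up and down. For 24 h against 0 h edgeR recovered 56% of sequences changed 4-fold, 98% of those changed 8-fold, 96% of those changed 16-fold and 92% of those changed 32-fold, and 3.39% of its calls were false. A balance of mostly falls, or 1 sequence rising to a large share of the reads, was not simulated. In a simulated comparison of 12 h with 0 h without any change it made 0 calls. For 24 h against 0 h, fry called a simulated list of 20 members moved 4-fold in 17 of 20 data sets and called 0 of 200 unmoved lists. The ratio interval covered the true ratio in 96.6% of 1800 simulated sites of 2 libraries. The permutation test across 75 families called 5.25% of unrelated data sets and 99% of those simulated with a correlation of 0.5, and weaker correlations were not simulated. The simulated values carried no counting noise, unlike the degradome sites with few reads. The alternatives tried were a replicate block, each library left out in turn, no filter and a filter of 50 reads, DESeq2's size factors, library totals without the 3 most abundant sequences, DESeq2 1.42.0, limma on log2 of the deposited normalized signal plus 1, only the 4 libraries compared, every listed entry, and for the degradome stricter site selections. An alternative without sequences that end in CCA was chosen after seeing the data.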

Results

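Small RNA and degradome libraries were compared between untreated rice leaves and leaves kept at 45 °C for 12 or 24 h, to find miRNAs whose levels differed after heat and the transcripts they cleave. No unheated leaves of 12 or 24 h are among the samples. Heat therefore cannot be told apart from elapsed time, such as the time of day or plant age. The line, HT54, is described in the labels as a heat-tolerant Indica breeding line. The listed miRNAs held 33623 and 102513 reads at 0 h (replicates 1 and 3), 147038 and 10314 reads at 12 h, and 119293 and 227965 reads at 24 h. These are sums over the miRNA list and not library totals, which are not given in the sources used here. Within a time point the log2 CPM values of the 2 libraries correlated with r = 0.917 at 0 h, 0.803 at 12 h and 0.882 at 24 h across sequences, and 12 h replicate 1 correlated more closely with both 24 h libraries (0.882 and 0.904) than with the other 12 h library. The degradome libraries held 12554074 raw reads at 0 h, 11033581 at 12 h and 12960708 at 24 h, of which 80.6%, 80.1% and 83.5% mapped to transcripts.

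After 12 h at 45 °C the miR396 family, which targets growth-regulating factor (GRF) genes, rose against 0 h by a log2 change of 1.30 ± 0.32 (SE, n = 2 libraries per time point, adjusted p = 0.0155, edgeR's quasi-likelihood test). The 12 h libraries of the family were unlike, at 210280 and 98388 CPM (replicates 1 and 3). As single sequences, its most abundant member osa-miR396e-5p (1.58, adjusted p = 0.407) and osa-miR396a-5p (1.16, adjusted p = 0.453) did not pass the same test. The families miR1850 and miR2606 fell, with log2 changes of −3.54 ± 0.82 and −5.20 ± 1.25 and the same adjusted p of 0.0155. So did miR5073, named after its values were seen, at −4.81 ± 0.97 with an adjusted p of 0.00801. osa-miR528-3p, the passenger strand of a monocot miRNA that targets copper proteins, fell from 2123 ± 1839 CPM to 238 ± 30.7 CPM (mean ± SD), a log2 change of −3.18 ± 0.81 with an adjusted p of 0.00653. osa-miR166d-5p, a passenger strand of the family that targets HD-ZIP III genes, fell with a log2 change of −3.35 ± 0.89.

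In all, 15 of 459 sequences changed at 12 h, 2 up and 13 down, and 61 reached an unadjusted p under 0.05. The other named falls were mtr-MIR2606c-p3_2ss8TG18GA (log2 change −5.04 ± 1.06), gma-MIR6300-p3_1ss8AG (−4.68 ± 1.05), osa-miR5073_R+1_1ss20AT (−4.64 ± 1.01), osa-MIR1850-p5_1ss18CT (−3.35 ± 0.84), gma-MIR6300-p3_1ss11AG (−2.90 ± 0.86), gma-MIR5368-p3_1ss4GA (−2.69 ± 0.84), gma-miR6300_R+1 (−2.60 ± 0.76) and osa-MIR169a-p3 (−2.55 ± 0.76). Both rises had few reads and are named after their values were seen. osa-miR396d had 52 reads at 12 h against 1 at 0 h, a pooled ratio of 45.5 (exact 95% interval 7.82 to 1833), and none of the 52 came from replicate 3. ghr-miR393_L+3R-1 had no read at 0 h and was at least 5.67-fold higher at 12 h, with an adjusted p of 0.029. osa-miR396d differs from the far more abundant osa-miR396e-5p by the substitution T20G (osa-miR396e-5p base first, counted from the 5′ end), and its reads were 0.153% of the sum of both at 12 h (exact 95% interval 0.115 to 0.201%), 0.105% at 24 h (0.0888 to 0.124%) and 0.0132% at 0 h (0.000335 to 0.0736%). Misread copies of osa-miR396e-5p were not excluded as a source of these reads. Of the families, 4 of 124 changed, 1 up and 3 down, with 16 at an unadjusted p under 0.05.

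The preset lists showed no shift in 1 direction at 12 h. By fry 0 of the 11 lists passed and 0 reached an unadjusted directional p under 0.05, and camera gave 0 at either level. The mixed test also gave 0 after adjustment, with 5 lists at an unadjusted p under 0.05 (smallest adjusted p 0.093). Among 23 auxin miRNAs 1 rose (ghr-miR393_L+3R-1), and adjusted over the list alone 2 rose and 1 fell. Among 10 copper miRNAs 1 fell (osa-miR528-3p), also adjusted over the list alone. Among 19 nutrient miRNAs 1 fell (osa-MIR169a-p3), and 1 rose and 2 fell adjusted over the list alone. Leaf development had 1 rise (osa-miR396d) and 1 fall (osa-miR166d-5p) among 55, the same counts adjusted over the list alone. Restricted miRNAs had 3 falls among 21, all of miR1850, also adjusted over the list alone. The sequences of 23 or 24 nt had 1 rise and 2 falls among 157, and the same adjusted over the list alone, while passenger strands had 1 rise and 4 falls among 67, and 1 and 5 adjusted over the list alone. That rise is osa-miR396d, which the deposited arm places on the 3′ strand although it differs by 1 base from osa-miR396e-5p of the 5′ strand. Phase transition, small RNA machinery, miR444 and the panicle triggers had 0 members past the threshold, and 0 adjusted over the list alone. Median, mean and test disagreed in sign for auxin (median −0.01, mean 0.29, test up), nutrient (0.09, 0.37, test down), phase transition (−0.18, 0.00, test down) and restricted miRNAs (0.51, −0.03, test up). The miR396 call did not pass without 0 h replicate 1 (log2 change 1.17), 0 h replicate 3 (1.61) or 12 h replicate 1 (0.62), nor in 5 of 8 other settings. That of miR1850 did not pass without 0 h replicate 1 (−2.96) or 12 h replicate 1 (−3.99), that of miR2606 without 0 h replicate 3 (−2.96) or 12 h replicate 1 (−2.81), and that of osa-miR528-3p without 0 h replicate 1 (−1.83) or either 12 h library (−2.85 and −3.27). The osa-miR166d-5p call did not pass without any 0 h or 12 h library (−3.70 to −2.92). Of the other named falls, with 1 of the 6 libraries left out in turn, the call was kept 1 time for gma-MIR5368-p3_1ss4GA (−8.85 to −0.93, and in 2 of 9 other settings) and 1 time each for gma-MIR6300-p3_1ss11AG, gma-miR6300_R+1 and osa-MIR169a-p3 (4 of 9 other settings each). It was kept 3 times for osa-MIR1850-p5_1ss18CT (−9.81 to −2.76) and 4 times for gma-MIR6300-p3_1ss8AG (−8.59 to −2.17) and mtr-MIR2606c-p3_2ss8TG18GA (−6.26 to −2.81), and in 3 of the 4 fits that tested it for osa-miR5073_R+1_1ss20AT. The rise of osa-miR396d was kept with 3 of 6 libraries left out and in 4 of 8 other settings. The number of changed sequences was 2 without either 0 h library, 0 without 12 h replicate 1 and 9 without 12 h replicate 3. With library totals that leave out the 3 most abundant sequences, 1 rose and 3 fell in place of 2 and 13, and the median of all sequences shifted by 0.25.

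After 24 h at 45 °C the miR396 family rose against 0 h, with a log2 change of 3.23 ± 0.34 (SE, n = 2 libraries per time point, adjusted p = 5.85e-07, edgeR's quasi-likelihood test). Its most abundant member, osa-miR396e-5p, had 48336 ± 14096 CPM at 0 h, 144240 ± 110171 CPM at 12 h and 547145 ± 173020 CPM at 24 h, and made up 46.5% and 34.7% of the listed reads of the 24 h libraries. As a single sequence it rose by a log2 change of 3.50 at 24 h (adjusted p = 0.00437, edgeR's quasi-likelihood test). The values of the family and of the sequence come from separate fits with different shared spreads. The SE of the family is therefore not the spread of its own libraries alone. The families miR393, which targets auxin receptor F-box genes (2.98 ± 0.81, adjusted p = 0.0195), miR172, which targets AP2-like genes (2.54 ± 0.81, adjusted p = 0.0414), and miR160, which targets auxin response factor (ARF) genes (1.83 ± 0.60, adjusted p = 0.0465), rose as well. The miR528 family fell, with a log2 change of −2.40 ± 0.72 and an adjusted p of 0.0315. Other family falls were those of miR2606 (−4.02 ± 0.95), miR8155 (−3.76 ± 0.90), miR1850 (−2.74 ± 0.75), miR8175 (−2.69 ± 0.77), miR894 (−2.35 ± 0.50), miR6300 (−2.03 ± 0.51) and miR9774 (−1.85 ± 0.62) among the families with at least 100 reads.

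**Figure D1:**
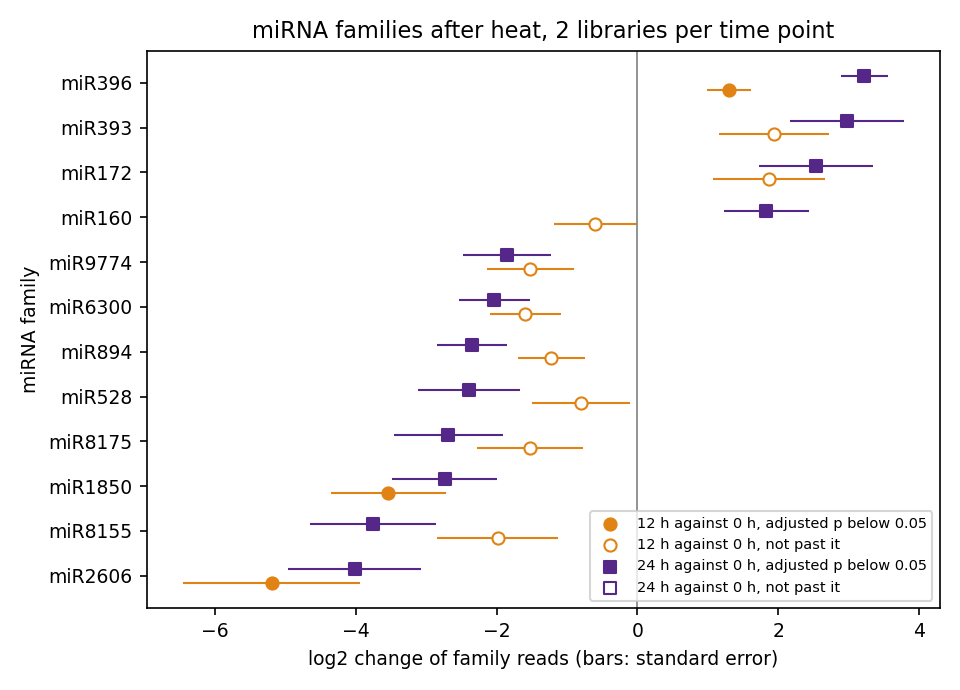
Log2 change of the summed reads of 12 miRNA families at 12 h (circles) and 24 h (squares) at 45 °C against 0 h, with the standard error as bars, from 2 libraries per time point. Filled symbols passed an adjusted p of 0.05. miR396 passed at both times, at 1.30 and 3.23, while miR160 passed at 24 h at 1.83 and had a value of −0.60 at 12 h.

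At 24 h, 44 of 459 sequences changed, 12 up and 32 down, and 103 reached an unadjusted p under 0.05. osa-miR393a rose from 1415 ± 745 to 11394 ± 5209 CPM (log2 change 2.99 ± 0.76, adjusted p = 0.00355) and osa-miR172a from 677 ± 77.7 to 4651 ± 607 CPM (2.78 ± 0.76, adjusted p = 0.00755). osa-miR160a-5p rose from 944 ± 559 to 7283 ± 4558 CPM (2.92 ± 0.76, adjusted p = 0.00437). osa-miR396a-5p (2.39 ± 0.76), osa-MIR169c-p3 (2.13 ± 0.73) and osa-miR444d.3 (2.10 ± 0.74, adjusted p = 0.049) rose too, as did osa-miR396d (misread copies not excluded), with 142 reads against 1, a pooled ratio of 75.3 (exact 95% interval 13.3 to 2996). osa-miR528-3p fell to 148 ± 56.1 CPM (−3.78 ± 0.78, adjusted p = 0.000115) and osa-miR528-5p from 19032 ± 3258 to 4051 ± 2510 CPM (−2.23 ± 0.75, adjusted p = 0.0349). Further named falls were osa-miR5073_R+1_1ss20AT (−4.95 ± 0.90), rgl-miR5139_L+3 (−4.46 ± 0.88), mtr-MIR2606c-p3_2ss8TG18GA (−4.07 ± 0.84), ath-miR8175_L+3_1ss5AT (−3.99 ± 0.80), cpa-miR8155_L-1 (−3.76 ± 0.80), osa-miR166a-5p (−3.31 ± 0.82), gma-miR408a-3p_L-1R+3 (−3.11 ± 0.78) and osa-miR171h_L-1R+1 (−2.84 ± 0.78). ppt-miR894_R+1, the most abundant sequence of the 0 h libraries, fell from 114823 ± 17811 to 14960 ± 10836 CPM (−2.94 ± 0.82, adjusted p = 0.00898). The sequences ppt-miR894_R+1, rgl-miR5139_L+3, ath-miR8175_L+3_1ss5AT and cpa-miR8155_L-1 end in CCA, the end of mature tRNAs. Of the 44 calls, 8 falls and 1 rise were of sequences with that end. Without all such sequences, an alternative chosen after seeing the data, 32 of the 44 remained, and the calls of that end were lost by construction. Of the 124 families, 18 changed, 5 up and 13 down, with 26 at an unadjusted p under 0.05. None of the 65 tested new candidates changed, with 3 at an unadjusted p under 0.05 by edgeR and 0 called by DESeq2.

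**Figure D2:**
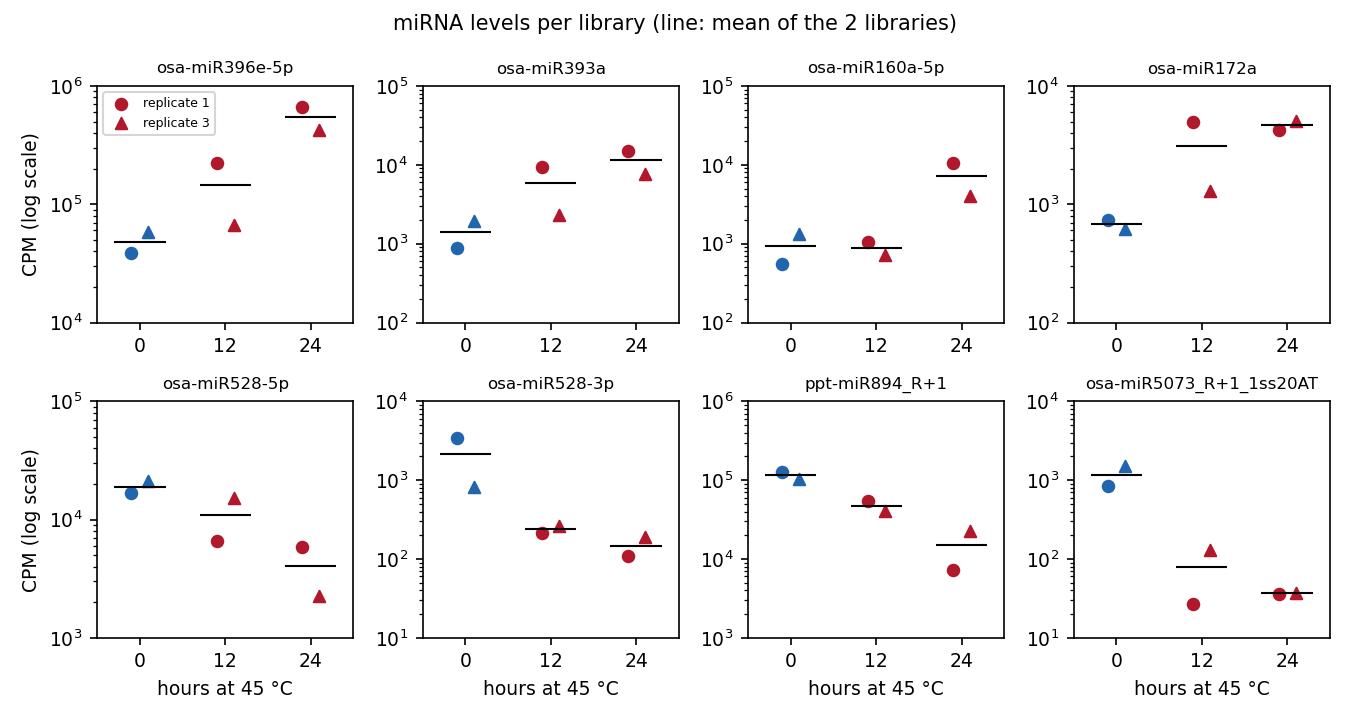
Level in CPM (log scale) of 8 miRNAs in each small RNA library against hours at 45 °C, with circles for replicate 1, triangles for replicate 3 and a line at the mean of the 2 libraries. osa-miR396e-5p lies between 38369 and 58304 CPM at 0 h and between 424802 and 669489 CPM at 24 h, and the 12 h libraries lie between, at 66337 and 222143 CPM.

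In the authors' precursor coordinates, whose genome build is not given in the sources used here, osa-miR396e-5p (TCCACAGGCTTTCTTGAACTG) was listed first on chromosome 2 from 35636546 to 35636721 on the minus strand, as 1 of 2 positions. osa-miR393a (TCCAAAGGGATCGCATTGATC) was listed on chromosome 1 from 2309149 to 2309263 on the minus strand, also as 1 of 2. osa-miR160a-5p (TGCCTGGCTCCCTGTATGCCA) has 4 listed positions, the first on chromosome 2 from 3511585 to 3511672 on the minus strand. osa-miR172a (AGAATCTTGATGATGCTGCAT) was listed first on chromosome 2 from 35143537 to 35143666 on the minus strand, as 1 of 2. Both strands of miR528 come from a single listed precursor on chromosome 3 from 1667328 to 1667415 on the plus strand. ppt-miR894_R+1 (CGTTTCACGTCGGGTTCACCA) has no listed position.

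The auxin list had 23 tested members at 24 h, of which 3 rose (osa-miR393a, osa-miR160a-5p and ghr-miR393_L+3R-1), 1 fell (osa-MIR167b-p3, 3 reads against 50) and 19 did not pass. Adjusted over the list alone, 4 rose and 1 fell. Its most abundant members, osa-miR160f-5p (1.51 ± 0.73) and osa-miR167d-5p_R+1 (−0.17 ± 0.71), did not pass. ghr-miR393_L+3R-1, named after its values were seen, was at least 6.44-fold higher than at 0 h. The copper list had 10 members, 0 rises and 4 falls, and 5 falls adjusted over the list alone. The falls were osa-miR528-3p, osa-miR528-5p, gma-miR408a-3p_L-1R+3 and osa-miR408-5p_L+1R-1, while osa-miR408-3p had −1.64 ± 0.73 with an adjusted p of 0.141. As families, miR408 (−1.72 ± 0.83), miR398 (−0.60 ± 0.64) and miR397 (−0.33 ± 0.65) did not pass. The nutrient list had 19 members with 2 rises, both of miR169 precursors, and 9 rises and 1 fall adjusted over the list alone. All its tested members except osa-miR827 were of miR169, so its values say little of other nutrient miRNAs. osa-miR827, of the phosphate response, had 1.72 ± 0.73 with an adjusted p of 0.111, but −1.16 without 24 h replicate 3, since the 24 h libraries (replicates 1 and 3) had 663 and 10047 CPM against 1830 and 1435 CPM at 0 h, and osa-MIR169a-p5 had −1.34 ± 0.72.

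Among 28 phase transition miRNAs 2 rose (osa-miR172a and osa-MIR529a-p5), also adjusted over the list alone, while osa-miR156a_L+1 (0.81 ± 0.76) and osa-miR156a (0.35 ± 0.71) did not pass. The miR529 family did not pass either (2.91 ± 1.10). Its 24 h libraries were unlike, with 10734 and 640 CPM (replicates 1 and 3) against 726 and 778 CPM at 0 h. Leaf development had 55 members with 3 rises, all of miR396, and 4 falls (osa-miR164e, osa-miR166a-5p, osa-miR166d-5p and osa-miR171h_L-1R+1), and 3 and 5 adjusted over the list alone. The abundant osa-miR166a-3p had 0.89 ± 0.74 and did not pass. Of 16 miR444 sequences 15 had positive values, 1 rose (osa-miR444d.3) and 0 passed adjusted over the list alone. osa-miR444f_1ss12CT (0.87 ± 0.75) and osa-miR444a-3p.2 (0.85 ± 0.71) did not pass. Restricted miRNAs had 3 falls among 21, all of miR1850, also adjusted over the list alone, while osa-miR1425-5p (1.34 ± 0.74) and osa-miR1862d (0.91 ± 0.71) did not pass. Small RNA machinery had 0 of 7 members past the threshold, also adjusted over the list alone, with 0.03 ± 0.74 for osa-miR168a-3p and 0.06 ± 0.74 for osa-miR168a-5p. The panicle triggers, which leaf should lack, had reads at 0 h (replicates 1 and 3), 6 and 38 of osa-miR2118b and 18 and 53 of osa-miR2118o_1ss1CT, both of the 3′ arm that holds the trigger, and 34 and 384 of osa-MIR2118e-p5_2ss12TA18CT of the 5′ arm, and had 0 of 3 past it, also adjusted over the list alone, with 0.68 ± 0.71 for osa-MIR2118e-p5_2ss12TA18CT and −0.86 ± 0.75 for osa-miR2118o_1ss1CT. The sequences of 23 or 24 nt had 2 rises and 6 falls among 157, and 1 and 3 adjusted over the list alone, with a fall of tae-miR9774_L+2R-1_1ss22GT (−2.25 ± 0.74). Passenger strands had 2 rises (osa-miR444d.3 and the near copy of a guide strand, osa-miR396d) and 7 falls among 67, and 3 and 8 adjusted over the list alone, with −0.69 ± 0.71 for osa-miR156c-3p. This list goes by abundance and is not free of guide strands, since it holds osa-miR2118b and osa-miR2118o_1ss1CT of the trigger arm. Whether further members, such as osa-miR168a-5p, are guide strands was not checked.

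No list moved in 1 direction at 24 h after adjustment over the 11 lists. By fry 0 passed and 1 (miR444) reached an unadjusted directional p under 0.05, and camera with an estimated correlation gave 0 at either level. The adjusted directional p was 0.295 for miR444 (median log2 change 0.89), 0.329 for copper (−1.61), 0.339 for auxin (1.09), 0.397 for small RNA machinery (−0.13) and 0.735 for nutrient (1.70), phase transition (0.26) and leaf development (0.28). It was 0.818 for the panicle triggers (−0.86) and 0.864 for restricted miRNAs (0.38), passenger strands (0.11) and the sequences of 23 or 24 nt (0.00, test down). In the mixed test of fry, change in either direction passed with an adjusted value of 0.000369 for leaf development, 0.0208 for passenger strands and 0.0313 for auxin, and not for copper, at 0.0567. The passenger list holds guide strands as well, so its value is not one of passenger strands alone. The number of changed sequences was 8 without either 0 h library, 13 without 24 h replicate 1 and 24 without 24 h replicate 3. The family calls did not pass for miR393 without 0 h replicate 1 (log2 change 2.53), for miR172 without 0 h replicate 1 (2.74), 0 h replicate 3 (2.44) or 24 h replicate 3 (2.32), for miR528 without the same libraries (−2.45, −2.29 and −1.94), and for miR160 without any library except 12 h replicate 1 (1.46 to 2.39). Nor did they pass for miR1850 without 0 h replicate 1 (−2.16) or either 24 h library (−2.62 and −2.72), for miR8175 without either 0 h library (−2.77 and −2.51) or 24 h replicate 1 (−2.05), for miR9774 without the same libraries (−1.98, −1.62 and −1.17), for miR8155 without 0 h replicate 1 (−3.49) or 24 h replicate 1 (−3.07), for miR2606 (−1.91) and miR6300 (−1.63) without 0 h replicate 3, and for miR894 without 24 h replicate 1 (−1.58). Of 8 other settings, 1 kept the call of miR9774, 4 that of miR160 and 7 those of miR172 and miR6300, while miR2606 was kept in 6 of the 7 that tested it. Of the single sequences, with 1 of the 6 libraries left out in turn, the call was kept 5 times for osa-miR528-3p (−2.43 without 0 h replicate 1), mtr-MIR2606c-p3_2ss8TG18GA (−2.02 without 0 h replicate 3), cpa-miR8155_L-1 and osa-MIR167b-p3, and 4 times for osa-miR396e-5p and osa-miR172a. It was kept 3 times for osa-miR393a, osa-miR160a-5p, osa-miR396a-5p, osa-MIR169c-p3 (0.26 without 24 h replicate 1), osa-miR166a-5p, gma-miR408a-3p_L-1R+3 and ppt-miR894_R+1, and 2 times for osa-miR528-5p (−3.09 to −1.55), osa-miR444d.3, osa-miR166d-5p, osa-miR171h_L-1R+1 and tae-miR9774_L+2R-1_1ss22GT. Of 9 other settings, 3 kept the calls of osa-MIR169c-p3 and osa-miR444d.3, 5 that of osa-miR528-5p and 6 that of tae-miR9774_L+2R-1_1ss22GT. With library totals that leave out the 3 most abundant sequences, the 24 h families split into 8 up and 12 down in place of 5 and 13.

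Between 12 and 24 h the miR396 and miR160 families rose, with log2 changes of 1.93 ± 0.32 (adjusted p = 0.000785) and 2.43 ± 0.62 (adjusted p = 0.0489) by edgeR's quasi-likelihood test (n = 2 libraries per time point). osa-miR160a-5p, which targets ARF genes, rose from 889 ± 246 to 7283 ± 4558 CPM, a log2 change of 3.00 ± 0.77 with an adjusted p of 0.048, and it was the only sequence of 459 to pass. Its relatives osa-miR160f-5p (2.30 ± 0.75) and osa-miR160e-5p (2.24 ± 0.74) had an adjusted p of 0.166 and did not pass. Also among the smallest p, and not past the threshold, were osa-MIR167b-p3 (3 reads against 30, 16.5-fold lower, exact 95% interval 5.13 to 84.5, but with a log2 change of 3.26 without 12 h replicate 1), rgl-miR5139_L+3 (−3.03 ± 0.94), osa-miR1320-3p (−2.38 ± 0.80), ath-miR8175_L+3_1ss5AT (−2.30 ± 0.75), gma-MIR6300-p3_1ss8AG (3.19 ± 1.05), osa-miR169r-3p (2.29 ± 0.80) and osa-MIR169c-p3 (2.21 ± 0.76).

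By edgeR 0 sequences fell between 12 and 24 h, with 15 lower and 21 higher at an unadjusted p under 0.05, and DESeq2 called 1 rise and 0 falls. Of the families, 2 of 124 passed and 9 reached an unadjusted p under 0.05. Among the lists only auxin had a member past the threshold, osa-miR160a-5p, with 4 rises and 1 fall adjusted over the list alone. Adjusted over the list alone, 2 nutrient miRNAs and 1 panicle trigger rose, and the other 8 lists had 0. By fry and camera 0 of the 11 lists moved in 1 direction, with 0 at an unadjusted p under 0.05, and the mixed test gave 0, with 1 (auxin) at an unadjusted p under 0.05. Median, mean and test disagreed in sign for small RNA machinery (0.23, −0.10, test down) and restricted miRNAs (−0.06, 0.11, test up). The miR396 call did not pass without 12 h replicate 3 (log2 change 1.23) or 0 h replicate 3 (1.85), and its value was 2.72 without 12 h replicate 1, while those of miR160 (2.14 to 2.61) and osa-miR160a-5p (2.18 to 3.25) did not pass without any library except 24 h replicate 3. In 7 of 8 other settings each of these calls did not pass.

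The calls at 12 h and 24 h overlapped. Both of the 2 rises at 12 h were among the 12 at 24 h, and 8 of the 13 falls were among the 32. Independent lists of these sizes share 0.0523 and 0.906 sequences on average, and simulated unchanged groups against the same 0 h libraries shared 0 in 20 data sets, which held 1 call in all and so say little about the overlap of calls. The log2 changes at both times correlated across sequences with r = 0.768 against 0.513 in the simulation, and their covariance was 1.36 against 0.36, a difference of 0.997. The 0 h controls were not split, because each part would hold 1 library, so part of the excess may come from the shared controls.

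The degradome tables listed 557 pairs of a miRNA family or new candidate and a target locus, over 519 loci. Of these, 50 pairs were of new candidates, and the others covered 80 families. Reads at copper protein transcripts targeted by miR528 went from 521 at 0 h to 23 at 12 h and 18 at 24 h, 19.9-fold and 29.9-fold lower after scaling to raw reads (24 h to 0 h ratio 0.0335, exact 95% interval 0.0197 to 0.0534). Those targeted by miR408 went from 1033 to 158 and 163, 5.75-fold and 6.54-fold lower. Sites of miR396 in GRF transcripts had 52, 10 and 12 reads, 4.57-fold lower at 12 h and 4.47-fold lower at 24 h (ratio 0.224, 0.109 to 0.424). In contrast, sites of miR169 in nuclear factor Y subunit A transcripts had 242, 289 and 771 reads (24 h to 0 h ratio 3.09, 2.67 to 3.58), those of miR159 in MYB transcripts 21, 35 and 68 (3.14, 1.90 to 5.39) and those of miR172 in AP2-like transcripts 44, 44 and 100 (2.20, 1.53 to 3.21). With 1 library per time point these differences compare libraries and not conditions. No transcript levels are among the samples, so a change of cleavage cannot be told apart from a change of the transcript.

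**Figure D3:**
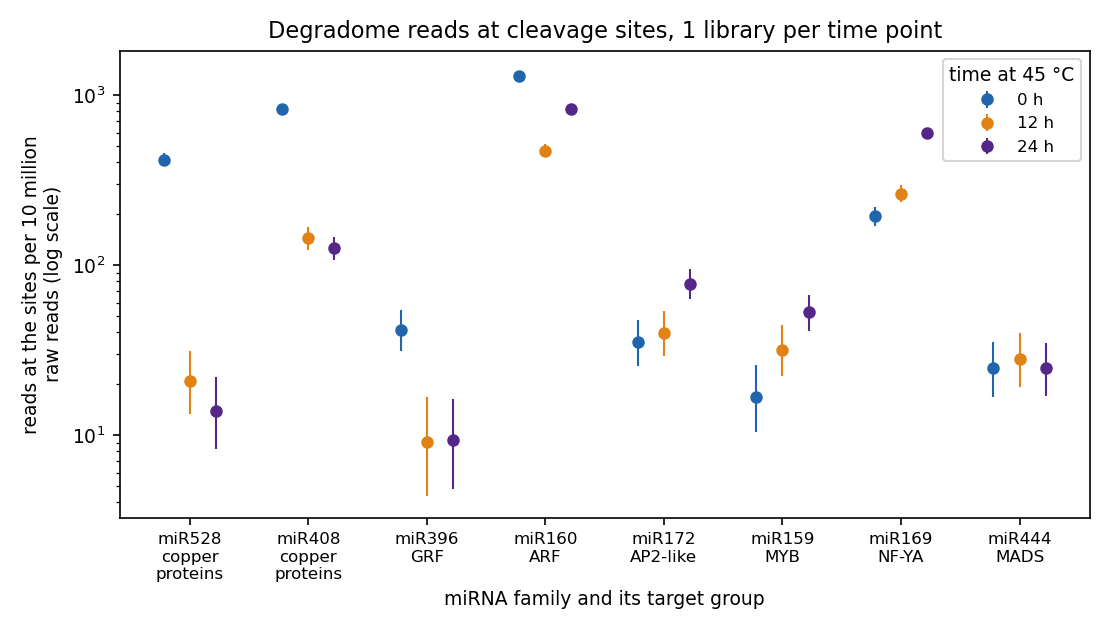
Degradome reads per 10000000 raw reads (log scale) at the cleavage sites of 8 target groups, named by the miRNA family and the authors' gene description, in the single library of each time point. Bars are exact 95% Poisson intervals and cover counting error only. Sites of miR528 in copper protein transcripts go from 415 to 20.8 and 13.9, while those of miR169 in nuclear factor Y subunit A (NF-YA) transcripts go from 193 to 262 and 595.

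Sites of miR160 in ARF transcripts had 1629 reads at 0 h, 518 at 12 h and 1067 at 24 h, a ratio to 0 h of 0.362 at 12 h and 0.634 at 24 h. Fewer reads at 12 h than at 0 or 24 h were also listed for miR171 and GRAS genes (253, 114 and 213 reads), miR166 and HD-ZIP genes (194, 62 and 151 reads) and miR164 and NAC genes (22, 6 and 19 reads). The miR166 sum counts reads shared by near-identical loci more than once. Summed over all 557 pairs, reads at the sites were 5776 at 0 h, 2589 at 12 h and 3749 at 24 h. These totals include the groups named here, so they do not tell whether the lower reads are particular to these groups. Sites of miR393 in F-box transcripts had 11, 11 and 12 reads, a 24 h to 0 h ratio of 1.06 (exact 95% interval 0.427 to 2.64), and those of miR444 in MADS-box transcripts 31, 31 and 32 reads, so that no difference was detectable at this depth. Sites of miR156 had 22, 23 and 32 reads and the site of miR398 in a copper/zinc superoxide dismutase had 29, 47 and 16. Fewer than 10 reads at every time point stood at the sites of miR397 in laccase transcripts (8, 3 and 1), miR319 in TCP (6, 2 and 1), miR827 (3, 1 and 5) and miR167 (1, 0 and 0).

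The single sites with the most reads were that of miR408 in LOC_Os08g37670, a cupredoxin (1032, 158 and 162 reads at 0, 12 and 24 h), that of miR160 in LOC_Os06g47150, described as auxin response factor 16 (892, 321 and 759), that of miR169 in LOC_Os03g48970, described as nuclear factor Y subunit A1 (217, 283 and 758), and that of miR528 in LOC_Os07g38290, a cupredoxin (505, 18 and 15). All of these were category 0 in each library. The site of miR396 in LOC_Os02g53690, described as growth-regulating factor 5, had 18 reads at 0 h, 0 at 12 h (at least 5.27-fold lower) and 1 at 24 h (18.6-fold lower, ratio 0.0538, exact 95% interval 0.00129 to 0.341). The site of miR172 in LOC_Os07g13170, related to AP2.7, had 0, 2 and 12 reads, at least 3.87-fold higher at 24 h. The site of miR1425 in LOC_Os10g35436, described as rna processing factor 2, had 19, 4 and 40 reads. That of miR444 in LOC_Os05g47560, a homolog of the kinase STN7, had 26, 73 and 50. Near-identical HD-ZIP loci, LOC_Os10g33960 (90, 31 and 72 reads) and LOC_Os03g01890 (89, 31 and 72), share reads, so the value of each is uncertain. The sum given for miR166 and HD-ZIP genes counts both loci and is uncertain as well.

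Reads were found for 325 pairs at 0 h, 305 at 12 h and 305 at 24 h, and 119 pairs had reads in all 3 libraries. Category 0 held 46 of the pairs at 0 h (14.2%, Wilson 95% interval 10.8 to 18.4%), 33 at 12 h (10.8%, 7.81 to 14.8%) and 39 at 24 h (12.8%, 9.50 to 17.0%), intervals that overlap. A single read was the whole evidence for 160, 154 and 154 pairs. By the rule of size, 1 of 49 pairs was higher and 14 lower at 12 h than at 0 h, 4 of 50 higher and 9 lower at 24 h than at 0 h, and 4 of 43 higher and 0 lower at 24 h than at 12 h.

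Across families, no relation of the miRNA change and the median change of degradome reads was detected by permutation tests for 3 contrasts. These tests found a simulated correlation of 0.5 in values without counting noise and were not tried on weaker ones. Since 392 of the 557 pairs had at most 3 reads, a true relation could be missed more often here than in the simulation. At 24 h against 0 h Pearson's r was 0.146 over 77 families (permutation p = 0.207, adjusted 0.621) and Spearman's rho 0.174 (permutation p = 0.131, adjusted 0.391), and r was 0.177 without miR2606 and miR8155, the families farthest from the median miRNA change. At 12 h against 0 h r was 0.0366 over 75 families (permutation p = 0.758, adjusted 0.764) and rho 0.0736 (permutation p = 0.529, adjusted 0.672), with r = 0.0794 without miR2606 and miR1850. At 24 h against 12 h r was 0.0356 over 75 families (permutation p = 0.764, adjusted 0.764) and rho 0.0498 (permutation p = 0.672, adjusted 0.672), with r = −0.0526 without miR1320 and miR160. Families are not independent replicates of the treatment.

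In the authors' deposited table, 44 of the 483 sequences had an analysis of variance p under 0.05, with a smallest value of 0.454 after Benjamini-Hochberg adjustment, and 12 of these were among the 49 sequences that changed at 12 or 24 h here.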

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

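The 2 tests of explanations in this part were chosen after the results were seen, while the comparison of 24 h with 12 h and its alternatives were planned. For 1 sequence and 2 families the change at 24 h differed from that at 12 h by a test of the difference itself, which is the comparison of 24 h with 12 h: osa-miR160a-5p by a log2 value of 3.00, the miR160 family by 2.43 and the miR396 family by 1.93. For osa-miR160a-5p and miR160 the values at 12 h against 0 h were −0.07 and −0.60, and the calls were kept in 1 of 8 other settings and with 1 of 6 libraries left out.

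The pattern weighed here is the rise of miR396 over 0 h and again from 12 to 24 h. Whether scaling was drawn off by the few sequences that take most reads was not decided for the 24 h rise. With library totals that leave out the 3 most abundant sequences the family rose by a log2 change of 3.37. Those totals leave out miR396 itself, which can hardly lower its rise, so the test could not have shown such an effect. The difference of 24 h from 12 h was then 1.63 and no longer passed (adjusted p = 0.155, edgeR's quasi-likelihood test). Whether a single 12 h library sets the size of the 24 h against 12 h difference stays open, with a log2 change of 1.23 without 12 h replicate 3 (adjusted p = 0.622 by edgeR's quasi-likelihood test, range over alternatives 1.06e-10 to 0.656) and 2.72 without 12 h replicate 1. A hypothesis is that miR396 accumulates with time in heat, which no test here decides and for which unheated leaves of the same hours are lacking. The 24 h rise is the firmer part, kept in 8 of 8 other settings. Its log2 change ranged from 3.08 to 3.46 over these settings and with each library left out in turn. The call of 24 h against 12 h was kept in 1 of 8 other settings.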

How the results depend on the processing

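The alternative without sequences that end in CCA was chosen after seeing the data, and the other 20 settings were planned. Of 132 counts and relations over these settings 67 kept their size or side of the threshold. Of the reported single sequence values under other settings, 453 of 539 kept their direction and side of the threshold, 78 lost the call, 1 gained one and 7 turned in direction, and 170 of 206 family values and 47 of 51 list values were kept. The values that turned were all short of the threshold: osa-miR160a-5p at 12 h with a filter of 50 reads (0.0340), library totals without the 3 most abundant sequences (0.23) and only the 4 libraries compared (0.0682), osa-miR168a-3p at 24 h with the replicate block (−0.0552), limma (−0.16) and CCA left out (−0.0504), osa-miR168a-5p with CCA left out (−0.0120), the list test of restricted miRNAs with the replicate block at 12 h (median 0.47) and camera at 24 h against 12 h (−0.0558), that of 23 or 24 nt at 24 h with DESeq2's size factors (0.0749) and camera (0.00491), and the relation across families at 12 h with at least 10 reads (rho −0.0883). Same-numbered libraries deviated from their group means with correlations of −0.12, 0.15 and −0.22. With 2 libraries per group the deviations mirror each other, so these values cannot exclude that the replicate numbers pair the samples or mark a shared batch. With the replicate block 7, 29 and 0 sequences changed at 12 h against 0 h, 24 h against 0 h and 24 h against 12 h, and 1 family in the last. In the order of these contrasts, a filter of 50 reads gave 0, 12 and 0 sequences, and 1 family at 12 h and 0 at 24 h against 12 h, with osa-miR528-3p at 12 h at −3.21 in place of −3.18 and no longer past the threshold. Limma on the deposited normalized signal gave 3, 9 and 0 sequences and 2, 10 and 0 families. For 24 h against 12 h, no filter, DESeq2's size factors, library totals without the 3 most abundant sequences and only the 4 libraries compared each gave 0 sequences and 0 families, DESeq2 gave 1 family, and leaving out CCA gave 0 sequences. At 12 h against 0 h library totals without the 3 most abundant sequences gave 4 sequences and only the 4 libraries compared 7. Every listed entry, repeats included, gave 73 at 24 h against 0 h and 4 at 24 h against 12 h, where repeats count again. The causes of these differences were not tested. With each library left out in turn, and the lone library assumed to vary like the other groups, the changed sequences ranged from 0 to 15 at 12 h, from 8 to 58 at 24 h and from 0 to 3 at 24 h against 12 h, the families from 0 to 13, from 5 to 23 and from 0 to 4, and the lists from 0 to 0, from 0 to 3 and from 0 to 5, the highest list counts without 12 h replicate 1. There 259 of 374 sequence values kept direction and side, 97 lost the call, 6 gained one and 12 turned in direction, of which 1 had passed, osa-miR396d at 12 h, with a log2 change of −2.39 without 12 h replicate 1, the library that holds its 12 h reads, and up to 7.44 without 0 h replicate 3. The others that turned ranged from −0.57 to 0.67 for osa-miR160a-5p at 12 h, at 24 h from −0.84 to 0.29 for osa-miR167d-5p_R+1, −1.16 to 2.58 for osa-miR827, −1.30 to 0.82 for osa-miR168a-3p, −0.13 to 0.24 for osa-miR168a-5p and −0.12 to 1.99 for osa-MIR2118e-p5_2ss12TA18CT, and from −4.46 to 3.26 for osa-MIR167b-p3 at 24 h against 12 h. Family values were kept in 108 of 156 and list values in 83 of 102. The medians of lists whose test turned ranged at 12 h from −0.24 to 0.32 for auxin, −2.30 to 0.64 for nutrient and 0.0747 to 0.906 for restricted miRNAs, at 24 h from −0.0126 to 0.799 for restricted miRNAs, −1.59 to −0.38 for the panicle triggers, −0.33 to 0.42 for 23 or 24 nt and −0.0338 to 0.607 for passenger strands, and at 24 h against 12 h from −0.38 to 0.23 for small RNA machinery and −0.40 to 0.28 for restricted miRNAs. At 24 h the calls of miR396, ath-miR8175_L+3_1ss5AT and rgl-miR5139_L+3 were kept in every setting that tested them and without each library, while miR9774 was kept in 1 of 8 settings and miR160 in 4 of 8. Of the degradome pairs, 55, 39 and 46 remained at 0, 12 and 24 h in categories 0 and 1, 43, 30 and 38 with at least 10 reads, and 53, 40 and 45 with an authors' p of at most 0.05. The relation across families had no call in any setting. Pseudocount alternatives were not run, because counts were tested. The library with the fewest reads was 12 h replicate 3, with 10314.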

Other observations

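The tests of depth, of scaling for sequences ending in CCA and of the tRNA class were chosen after the results were seen, while those of replicate likeness at equal depth and of sequences without a genome location were set before. The families miR894 and miR6300, first described in other plants, had the highest mean levels of untreated leaves. The miR6300 family went from 112441 ± 29179 CPM at 0 h to 27488 ± 3390 CPM at 24 h (SD, n = 2 libraries), over 17 sequences. By the authors' class tables, 16 of 116 conserved sequences fell and 2 rose at 24 h, against 16 falls and 10 rises among 275 known rice sequences, a difference that was not tested.

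In the degradome, 6 pairs had a heat shock annotation, with at most 8 reads and none in category 0. New candidates had 50 pairs over 22 candidates, of which 1 was category 0 and 6 had at least 10 reads. The reads at the site of miR1425 in LOC_Os10g35240 were 6, 3 and 27 at 0, 12 and 24 h, beside 19, 4 and 40 in LOC_Os10g35436.

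Fewer sequences changed at 12 h (15) than at 24 h (44). Lower depth of the 12 h libraries is argued against as the whole account, since with the 24 h libraries thinned to the 12 h reads the median was still 38 changed sequences (range 26 to 43 over 20 thinnings). Whether unlike 12 h replicates contribute stays open. The fit shares its spread over all time points, so a lower correlation at 12 h need not mean fewer calls there. At 10315 reads per library the 12 h pair correlated with a median r of 0.841 against 0.902 at 0 h and 0.854 at 24 h. It was lowest in 20 of 20 thinnings, though only just below the 24 h pair. At that depth 12 h replicate 1 was closest to 24 h replicate 3 (0.873) and 12 h replicate 3 to 0 h replicate 1 (0.868). A slower response of the plants at 12 h stays open and was not tested.

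Sequences that end in CCA, the end added to mature tRNAs after transcription, had a median log2 change of −0.96 at 12 h and −0.87 at 24 h over 30 members. At 12 h 0 of the 30 passed by edgeR, also adjusted over these sequences alone, with 9 lower and 0 higher at an unadjusted p under 0.05 and 0 called by DESeq2, and at 24 h 8 fell and 1, osa-miR160a-5p, rose, while without the miR160 sequences the 24 h median was −1.02 over 27 members, with 0 rises and 8 falls by edgeR. A scaling shift from the rise of miR396 is argued against as the whole account. Such a shift would move all sequences alike, and the sequences without that end had a median log2 change of 0.03 at 24 h. The median of those with it lay at the percentile 0.04 of 10000 random lists matched on abundance. That percentile is overstated, because the list was chosen after seeing the data and holds related sequences, such as those of miR8175. Fewer tRNA fragments may account for the pattern, as the tRNA class in the authors' deposited table went from 1.46% of reads at 0 h to 0.769% at 12 h and 0.984% at 24 h, but the fall was not particular to tRNA, since rRNA (5.13%, 3.01% and 4.40%), snoRNA (0.120%, 0.0833% and 0.0972%), other Rfam RNA (0.475%, 0.285% and 0.430%) and repeats (0.154%, 0.0868% and 0.131%) went the same way, while snRNA (0.0520%, 0.181% and 0.0432%) was higher at 12 h and mRNA (4.37%, 2.91% and 5.88%) at 24 h, and the classes sum to 100.3%, 109.8% and 118.1% and so are not plain shares. Reads of another organism stay open as well, because 13 sequences without a genome location and without CCA had a median of −0.86, 5 without a location and with CCA had −2.94, and 25 with both a location and CCA had −0.81.

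The deposited chi-square p of the degradome sites treats divided reads scaled to library size as if they were counts. Recomputed that way, it matched the deposited value within 10% on the log10 scale, with a margin of 0.05 added, for 100% of 1209 entries. The others of the 1429 entries had no deposited p with a finite log10 and were not compared. By it 555 of 557 pairs had a p under 0.05, including all 392 pairs with at most 3 reads. The same question asked of the reads themselves, with 10000 multinomial draws per pair, gave 65 pairs at an unadjusted p under 0.05, 3 of them among those 392, and 40 after Benjamini-Hochberg adjustment. Such a test compares these libraries and not the conditions.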
